A study of Medicago truncatula with 2 samples.

How the data were processed

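Roots of Medicago truncatula, a model legume, of the ecotype Jemalong A17 were compared in 2 degradome libraries. Per the labels, 1 library came from roots inoculated with the arbuscular mycorrhizal fungus Glomus intraradices and taken 3 weeks after inoculation, and 1 from roots without the fungus. No harvest time was recorded here for the roots without the fungus, so whether the 2 groups were of the same age was not known. The plants received 20 µM phosphate, and the inoculum was 10% of the substrate by volume, per the labels' protocols. A degradome library holds the 5′ ends of uncapped, polyadenylated RNA fragments. Each tag therefore marks a position where an RNA was cut or decayed, and a cut guided by a microRNA (miRNA) leaves a 5′ end opposite nucleotide 10 of that miRNA. Per the labels' protocols, poly(A) RNA was purified from total RNA and the libraries were built from it by a published degradome method.

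The authors deposited a table per library with each tag sequence and its read count, in whole numbers and not normalised. The base caller, adapter trimming and any filter used by the authors are not given in the sources used here. The tags were 20 or 21 nt long. The colonised library held 7777769 reads in 4594450 distinct tags, and the non-colonised library held 5620484 reads in 2897498 distinct tags. Tags of 20 and 21 nt were merged on their first 20 nt. Tags with an undetermined base (N) were left out. They made up 0.0874% of the colonised reads and 1.60% of the non-colonised reads, and this left 7771569 and 5531085 reads.

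No genome or transcript sequence was used here. Tags were therefore not assigned to genes or to genome positions, and tags took the place of genes, as fixed before the data were examined. The gene lists, the share of tags in annotated transcripts, the reading frame of 5′ ends and the profiles around stop codons and exon junctions, all planned, were not analysed here. With 1 library per group there were no replicates, so no p-value was computed. Each ratio carries an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only, and each difference compares these 2 libraries and not the conditions. Amplified reads are not independent molecules, so the intervals are too narrow to that extent. Where a library had 0 reads, a fold was computed against a floor of 3 reads.

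Tags with at least 50 reads in both libraries together were compared after scaling to the reads of each library. A tag counted as higher or lower when its whole interval lay beyond 2-fold. The median log2 ratio of tags seen in both libraries was -0.31, and changes are given relative to that median tag where stated. The rule fixed beforehand named the 12 tags with the highest and the 12 with the lowest bound, and for each miRNA family the site with the most reads. Sequences are printed only for tags with at least 20 reads in each library and a ratio under 16-fold, and for miRNA sites, because tags seen in practically 1 library only can come from another organism. The tags named with their sequence under that restriction were chosen after the values were seen. Counts for 10524 tags were simulated with Poisson counting error only, the error that the interval assumes. On these, the 2-fold rule recovered 43.3% of 67 tags changed 3-fold, 77.6% of 67 changed 4-fold and 100% of 66 changed 8-fold. It called 0 unchanged tags there, which gives no rate of false calls for real libraries.

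A list of 34 sequences from 27 small RNA families, entered by hand from general knowledge before the data were examined, was used to find cleavage signatures. In the planned form, the first 10 nt of a tag had to be the reverse complement of nt 1 to 10 of the miRNA, and the count was set against 100 shuffles of each sequence. A site, defined after the data were examined because no transcripts were used, had to meet 4 conditions. The pairing over nt 1 to 10 had a penalty of at most 1, with 0.5 for a G:U pair and 1 for a mismatch, both doubled at nt 2 to 13. The tag had at least 5 reads in a library and more than every start position up to 5 nt away on either side, read from tags overlapping by at least 15 nt. Bases upstream, where overlapping tags gave them, kept the total penalty at 4 or less. The tag did not lie within 1 mismatch of a tag with at least 20 times its reads. Site reads of each family were set against 100 shuffles of its sequences under the same rule. The shuffles permuted single bases, so the composition of adjacent base pairs, planned to be kept where possible, was not kept. Tag starts were uneven in composition, with C as first base in 8.14% of colonised and 7.68% of non-colonised reads. The shuffles can therefore misstate what chance would give. A miRNA site under the site rule is a match of sequence and position, and the transcript it lies in was not determined. At most 5 bases upstream were read, so pairing with the 3′ part of the miRNA was never scored. In 200090 simulated tags, exact pairing and the peak condition recovered 30 of 30 isolated planted sites and 0 of 30 with a taller neighbour. Imperfect pairing and the conditions on upstream bases and on abundant tags were not simulated. A miR396 pairing with 1 unpaired target base and a miR171 position 3 nt upstream were added after the data were examined. List medians were set among 10000 random lists of the same size, matched on read level in 20 bins.

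Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives were median-ratio and TMM scaling, other read minimums, tags seen once left out, tags with N kept, the tag lengths kept apart, overlapping tags merged, equal depth, and stricter or looser pairing, and the closing section gives their effect.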

Results

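The 5′ ends of uncapped RNA were counted in 1 library from Medicago truncatula roots colonised by Glomus intraradices and in 1 library from non-colonised roots. Neither group had a replicate. After tags with an undetermined base were left out, the colonised library held 7771569 reads and the non-colonised library 5531085 reads. Merged on their first 20 nt, these made 4248921 and 2607205 distinct tags. The 2 libraries shared 820957 of the 6035169 distinct tags. Shared tags held 40.2% of the colonised reads and 54.9% of the non-colonised reads. Before merging, 76.0% of the colonised tags and 67.3% of the non-colonised tags were seen once. The 10 most abundant tags took 0.686% of the colonised reads and 0.879% of the non-colonised reads.

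The first question was whether miRNA-guided cut positions could be seen in the roots. Reads at the 5′ ends that 27 conserved and legume small RNA families would leave exceeded those of all 100 shuffles in both libraries. Tags starting with the exact complement of nt 1 to 10 held 1308 reads in the colonised library, against a median of 201.5 and a highest value of 435 over 100 shuffles. In the non-colonised library they held 1072 reads, against a median of 147.5 and a highest value of 294. Under the site rule, which also asked for a local peak, 53 sites of 19 families were found in the colonised library and 48 sites of 17 families in the non-colonised library. Shuffled sequences gave a median of 8 sites in each library, with at most 21 and 22, so some of the sites with few reads are expected by chance. Across both libraries there were 65 sites of 20 families, and 36 of them were peaks in both. Only 15 of the 65 had at least 4 known bases upstream, so most sites rest mainly on pairing over nt 1 to 10.

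The paired stretch lay at the very 5′ end of the tags, where a cut opposite nt 10 places it. Local peaks with this stretch at the first base held 1984 colonised reads and 1825 non-colonised reads. With the stretch placed 1 to 9 nt further in, the median was 309 reads and 331 reads. The highest of these other positions was 3 nt in, with 901 and 566 reads, and most of those reads belonged to miR171.

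**Figure D1:**
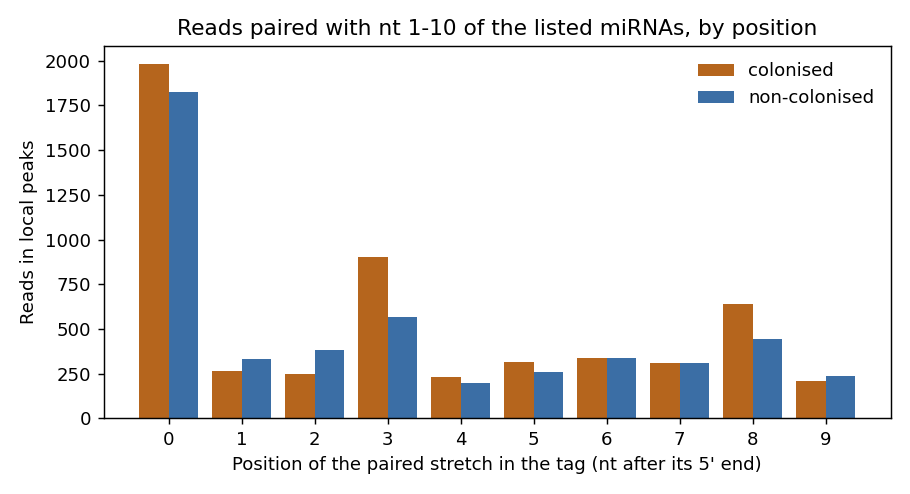
Reads in local peaks (y axis) that pair with nt 1 to 10 of the listed miRNAs, by the position of the paired stretch in the tag in nt after its 5′ end (x axis), for the colonised library and the non-colonised library. Position 0 held 1984 and 1825 reads, and position 3 held 901 and 566 reads.

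Under the rule applied to all families, miR2118 had the most reads at its sites and miR160 had more than miR396. Of the miR2118 reads, 503 and 521 lay in a tag with a penalty of 1 and no known base upstream. With exact pairing over 10 nt, miR160 held more than miR2118, with 309 and 204 reads against 241 and 146. A bulged form, added after the data were examined and searched for miR396 alone, held more than any of these. miR396 is known to act on growth-regulating factors, a family of transcription factors that promote cell proliferation. Their known miR396 site carries 1 unpaired base. In that bulged form, 11 sites held 2734 reads in the colonised library and 4674 reads in the non-colonised library. Shuffles of miR396 with the same bulge gave a median of 7 reads in both libraries together and at most 188. The main tags were AGCCTGTGGAAGTTGTTAAA with 1244 and 2396 reads, AGCCTGTGGAATCTTCTTCT with 816 and 843 reads, AGCCTGTGGAATCACAAACT with 357 and 953 reads, and AGCCTGTGGAAGGCCAATCT with 216 and 351 reads. Without the bulge, 10 sites, of which 3 had no penalty over nt 1 to 10, held 119 and 213 reads, led by AGCTGTGGAATTGGTAGATG with 48 and 65 reads. The 5 known bases upstream of this leading tag added a penalty of 3.5, near the limit of 4.

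Sites were also found for families known to target genes of auxin signalling. miR160, known to cut transcripts of auxin response factors, had 5 sites with 288 colonised and 188 non-colonised reads. The leading tag was GAGCCAGGCATGATCTATTT with 189 and 87 reads, followed by GAGCCAGGCATGCTCATTAT with 49 and 68 reads. The trans-acting small RNA tasiR-ARF, which targets other auxin response factors, had 9 sites with 123 and 103 reads, led by AGGTCAAGAAATTCTTCTGT with 47 and 30 reads. For miR393, known to target auxin receptor F-box genes, the 1 site TCCCTTTGGATGTCCTCTTG had 17 and 6 reads. No site was found for miR167.

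Among the families known to target disease resistance genes of the nucleotide-binding, leucine-rich repeat class, miR2118 had 3 sites with 713 and 651 reads. They were GAATTGGTAAAGCCACTTTG with 503 and 521 reads, GAATCGGTAAACAGTGCAGA with 155 and 100 reads, and GAATCGGTAAACAGCATCGA with 55 and 30 reads. miR2109 had 5 sites with 51 and 75 reads, led by GATACTCGCAGAACTATTGT with 23 and 31 reads. miR1507 had the single site TGGAACGAGTGTAGCAGTTG with 5 and 7 reads.

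Families known to target other transcription factors followed. The 2 tags CGCGGCTCAATCACCAAATT, with 358 and 144 reads, and CGCGGCTCAATCACCAGCTC, with 311 and 185 reads, pair with miR171, which targets scarecrow-like GRAS genes, but begin 3 nt upstream of the position opposite nt 10. Their position was singled out after the values were seen. Shuffles of miR171 at that position gave a median of 20 reads in both libraries together, and 1 of 100 shuffles reached as many reads as miR171. miR171h, known to target NSP2, a GRAS gene of root symbiosis, had the site ATTCGGCTCAAGGACTTAGT with 54 and 30 reads. The leading miR169 tag TCCTTGGCTCATTACTTTGG, of a family that targets subunits of nuclear factor Y, had 48 and 11 reads. The leading miR172 tag TCAGGATTCTCCATTTCAGC, of the family that targets AP2-like genes, had 49 and 51 reads. For miR164, which targets NAC genes, TGCTTCTCCAACTCAATTGA had 12 and 23 reads.

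In phosphate and mineral nutrition, miR399, known to target the ubiquitin-conjugating enzyme PHO2 that restrains phosphate uptake, had 5 sites with 75 and 62 reads, led by TTCTTTGGCATCAGATCTCT with 35 and 39 reads. The remaining families with a site, which were miR156, miR159, miR168, miR319, miR394, miR395, miR397 and miR398, had from 5 to 19 colonised reads and from 0 to 19 non-colonised reads each. Chance was not excluded for miR156, miR159, miR393, miR394, miR395, miR397, miR398 and miR1507, where 7 to 23 of 100 shuffles gave as many site reads. For each of the other families with a site at most 2 of 100 shuffles did under the site rule, which was defined after the data were examined. In the form fixed beforehand, exact pairing over 10 nt, as many reads were reached by 48 of 100 shuffles for miR168, 22 for miR172, and 5 each for miR319 and miR399. Over 9 nt they were reached by 81 for miR168, 37 for miR172, 27 for miR399, 22 for miR171h, 15 for miR2109, 12 for miR319 and 8 for miR169, so chance is not excluded by that form for these 7 families. The miR169 and miR171h sites rest on imperfect pairing, since tags with the exact complement held 0 reads for either family. The leading tags of miR2118, miR2109, miR172, miR399 and miR168 also had a penalty of 1 over nt 1 to 10. No site was found for miR166, miR390, miR408 or miR828, and none for miR171 at the position opposite nt 10. For miR162, known to target the Dicer-like gene of miRNA processing, tags with the exact complement held 26 colonised and 84 non-colonised reads, a log2 ratio of -2.18 (95% interval -2.88 to -1.53) scaled to library totals. As many reads were reached by 2 of 100 shuffles, and by 13 of 100 when pairing was asked over 9 nt. Its leading tag, with 16 and 73 reads, was a local peak in the non-colonised library, with 51 reads at the highest neighbouring start. The bases upstream raised its penalty to 7, so it was not counted as a site.

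The second question was which cut positions differed between colonised and non-colonised roots. In summed reads, the miR396 sites were lower in the colonised library and the miR169 and shifted miR171 sites were higher. Relative to the median tag, the log2 ratio of the bulged miR396 sites was -0.95 (95% interval -1.02 to -0.89), and that of the sites without the bulge was -1.02 (-1.36 to -0.69). All 5 bulged sites with at least 50 reads were lower, from -0.23 for AGCCTGTGGAATCTTCTTCT (-0.37 to -0.09) to -1.60 for AGCCTGTGGAATCACAAACT (-1.78 to -1.42). The tag AGCTGTGGATATATAGTAGT, without the bulge and with a penalty of 1 over nt 1 to 10, had 9 reads against 57, at -2.84 (-4.04 to -1.82). The median ratio of 8 bulged sites lay at percentile 1.49 of random lists matched on read level in 20 bins. Few tags had reads like those of the leading sites, so the match can be only rough there. Among tags of like reads, the site with 3640 reads in both libraries together lay at percentile 0 of 3 tags. The sites with 1659, 1310 and 567 reads lay at percentile 25 of 16, 4 of 25 and 13.2 of 114 tags. The site with 122 reads lay at 10.6, and those with 38, 24 and 23 reads at 61.2, 22.5 and 49.5.

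The miR169 sites were at 1.32 (0.71 to 1.97) relative to the median tag, and the shifted miR171 sites at 0.84 (0.65 to 1.04). Of the 3 miR169 tags, only the leading one was higher beyond counting error, at 1.94 (0.98 to 3.04). Its penalty of 1 over nt 1 to 10 and 3 over the bases upstream lay at the limit of 4. The tag with 31 and 17 reads was at 0.69 (-0.21 to 1.63). The tag with 6 and 2 reads was at 1.40 (-1.08 to 4.75). The miR160 sites were at 0.43 (0.16 to 0.71), but they did not differ from equality without the shift to the median tag, at 0.12 (-0.15 to 0.40). Their tags went both ways. GAGCCAGGCATGATCTATTT was at 0.94 (0.56 to 1.32) and GAGCCAGGCATGCTCATTAT at -0.65 (-1.21 to -0.10). The miR164 tags went both ways too. TGCTTCTCCAATCCAATTGA had 27 reads against 3, and TGCTTCTCCATGTTTTCTCA had 22 against 4, while the leading tag was lower in the colonised library. The miR164 tags other than the leading one were chosen after their values were seen.

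The miR2109 sites were lower in their summed reads, at -0.74 (-1.28 to -0.20), of which 1 tag had 0 reads against 12. The median of 7 sites of miR1507, miR2109 and miR2118 lay at percentile 16.9 of random lists, inside their 95% range. For the next families the summed reads did not differ from the median tag beyond counting error. The miR2118 sites were at -0.05 (-0.20 to 0.11) and the tasiR-ARF sites at 0.08 (-0.31 to 0.47). The miR172 sites were at -0.11 (-0.64 to 0.42) and the miR399 sites at 0.09 (-0.41 to 0.60). The miR2118 tags went both ways. The tag with 503 and 521 reads was at -0.23 (-0.41 to -0.05). The tag with 155 and 100 reads was at 0.45 (0.08 to 0.83), and that with 55 and 30 reads at 0.69 (0.03 to 1.39). Some tasiR-ARF, miR172 and miR399 tags also differed from the median tag beyond counting error, though most did not. Scaled to library totals alone, the miR2118 sites were at -0.36 (-0.51 to -0.20). For miR171h the interval reached just below 0, at 0.67 (-0.002 to 1.36). Across 47 sites other than the bulged ones, the median lay at percentile 69.8 of random lists. These differences have no replicate check.

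**Figure D2:**
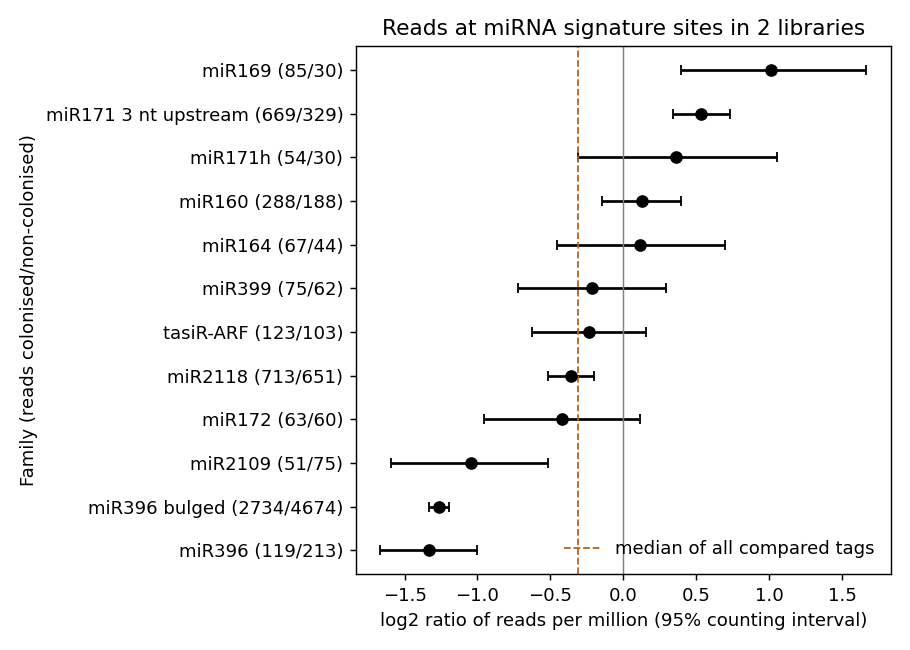
Log2 ratio of reads at miRNA sites, scaled to the reads of each library, colonised over non-colonised (x axis), for families with at least 50 reads (y axis, with reads of each library). Points are the ratio of the summed reads, bars are 95% counting intervals, and the dashed line marks the median tag at -0.31, with miR396 to its left and miR169 to its right.

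Among all RNAs, 10524 tags had at least 50 reads in both libraries together. Of these, 608 were higher in the colonised library by more than 2-fold and 829 were lower, and 9087 were neither. The higher tags made up 42.3% of those that differed. With median-ratio scaling the split was 775 higher and 444 lower, so that 63.6% were higher, and with TMM scaling it was 779 and 438, or 64.0%. Tags seen once held 44.9% of the colonised reads and 34.7% of the non-colonised reads, so leaving them out also changes the scaling, and it gave 717 higher and 534 lower. The prevailing direction therefore depended on the scaling. It also turned with a minimum of 20 reads, at 2984 higher and 2585 lower.

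The highest tags were practically confined to the colonised library. In all, 362 of the compared tags had 0 reads in the non-colonised library, and 0 had 0 reads in the colonised library. Of the 12 tags with the highest bounds, 8 were among them, and the 12 had 423 to 15757 reads in the colonised library and 0 to 21 in the other. The most abundant had 15757 and 21 reads, a ratio of 534-fold. The tag with 1665 reads and 0 in the other library was at least 395-fold higher against a floor of 3 reads, and the lower bound of its 95% interval was 8.33 on the log2 scale, a smaller fold. Tags absent from the non-colonised library held 0.467% of the colonised reads, and their mean GC content was 34.4% ± 11.6 (SD over 362 tags), against 37.2% ± 10.3 (SD over 6995 tags) for tags within 2-fold. The 12 tags with the lowest bounds had 49 to 530 reads in the non-colonised library and 2 to 72 in the colonised library.

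Sequences are given among the 8330 tags with at least 20 reads in each library and a ratio under 16-fold, a restriction that leaves out tags near 0 in either library. By the 2-fold rule, scaled to library totals, 32 of the 8330 were higher in the colonised library and 418 lower. A minimum of 20 reads is a larger share of the smaller, non-colonised library, so the restriction bore harder on higher tags. This split therefore does not give the prevailing direction. Without the restriction it was 608 and 829, or 775 and 444 with median-ratio scaling. The 12 highest were 4.59-fold to 5.85-fold above the median tag. They included GAGTTTCTGTGCTCGTTATC with 278 and 43 reads, TGCAATGGGTTATGAGAAGC with 159 and 24, GTTATCCTAATTCTGATATC with 145 and 22, TATCTCACTCCATTAATGGA with 199 and 34, GTGTTAACTGGAACTCAAGG with 205 and 36, and TGATATCGAACATGGCTGGT with 132 and 21. The 12 lowest were 6.71-fold to 10.4-fold below the median tag. They included GTAACAAAAAAAAATGTTGT with 33 and 302 reads, TGATCTTCTGATGTAGCTCT with 31 and 261, TGATGAATAATTAAGTGTTT with 72 and 530, CAGATAACTACCGTTGATGA with 68 and 475, AGTTTGTGAGAATTTGTGAA with 40 and 300, and GAGCGATTCGGATTCCGATG with 40 and 298. The genes these tags lie in were not analysed here.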

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

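The conserved sequence cores behind the classes below were chosen after the tags were seen, as were the tests on bacterial RNA and on depth. The tests on errors and on the fungus were set beforehand. Reads with the core of a fungal-type 5.8S ribosomal RNA, outside the plant measurement, were 184-fold more frequent in the colonised library after scaling to library size, with 1036 reads against 4. Tags with the sequence of a mature miRNA, which the comparisons of cut sites do not use, also appeared. In libraries of polyadenylated RNA fragments they do not measure the levels of mature miRNAs. The miR159 sequence TTTGGATTGAAGGGAGCTCT was 2.02-fold more frequent in the colonised library, with 981 reads against 346, and the miR162 sequence TCGATAAACCTCTGCATCCA was 4.17-fold more frequent, with 41 against 7. Tags with a C box, the motif near the 5′ end of a class of small nucleolar RNAs, were 1.37-fold more frequent with the motif 4 nt after the tag's first base and 1.26-fold with it 5 nt after. Plant-type 5.8S ribosomal RNA was 1.07-fold and tags with a run of at least 8 A were 1.08-fold more frequent in the colonised library.

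A block of 362 tags with at least 50 reads had none in the non-colonised library. Sequencing errors of abundant tags could at most give a small part, since 2.76% lay within 1 mismatch of a tag with at least 20 times the reads. A difference in depth alone, with counting error only, gave an expected number of 1.67e-09 compared tags with 0 reads in the other library. The minimum of 50 reads fixed this outcome in advance, so it shows only that depth with counting error cannot give such tags. The test on bacterial RNA in the colonised sample cannot decide. The conserved bacterial 16S start was 0.159 times as frequent there as in the other library. The 18S start was lowered alike, at 0.182 times, so the drop was not particular to bacteria. RNA of the fungus may account for the block as a biological explanation, but its test did not decide, because tags with at least 10 reads in 1 library alone were 2.77 times as many in the colonised library at equal depth, between the bounds set beforehand. It stays open, since no fungal genome or transcript was used to place the tags and any other organism in that sample was not tested. The fungal-type 5.8S core, with 1036 colonised reads against 4, goes with RNA of a fungus in that library. That core does not tell where the 362 tags came from.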

How the results depend on the processing

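No paired analysis was possible because each group had 1 library, and no library could be left out. Choices fixed beforehand that need transcripts (distinct positions per gene, the most abundant position left out, tags of several genes shared, 1 mismatch, site reads as a share of their transcript) were not run, nor those of the gene lists, transcript shares, reading frame and stop codons. Of the settings used, those on N, tag length, errors, merging, equal depth of the tag comparison, nt 1 to 10 penalties, scaling of site reads and added site forms were chosen after the data were examined. Against 608 higher and 829 lower tags, lower tags numbered 444 with median-ratio and 438 with TMM scaling, and with tags seen once left out, which changes the totals, 717 were higher and 534 lower. A minimum of 20 reads gave 2984 higher and 2585 lower, no minimum 6177 and 10305, and 200 reads 50 and 116, and the cause of the turn at 20 reads was not tested. Higher tags numbered 398 with overlapping tags merged and 347 at equal depth. Against 53 colonised and 48 non-colonised sites, at least 2 reads gave 157 and 147, at least 10 reads 33 and 31, no penalty over nt 1 to 10 gave 32 and 26, a penalty of at most 2 gave 96 and 88, and a position within 1 nt gave 193 and 169, with 3 positions counted. The log2 ratio of all reads at listed sites, -0.29, changed sign to 0.018 with median-ratio and 0.024 with TMM scaling, and was -0.83 with the added miR396 and miR171 forms. In the other 23 alternatives to these results, values stayed within 1.5 times of a count, inside the interval of a ratio, or above every shuffle. Among these, equal depth lowered the colonised sites to 42, below the 48 of the other library, so the order of the site counts turned. Among the named families and tags no ratio with an interval on 1 side of 0 changed sign under either scaling. Depth limits sites with few reads, where the intervals span several-fold.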

Other observations

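A motif of C/D small nucleolar RNAs stood at preferred positions of the tags in both libraries. The RNAs these tags came from were not determined. The C box motif was found 4 nt after the first base in 20953 colonised and 10870 non-colonised reads, and 5 nt after it in 18393 and 10425 reads. At the other positions from 0 to 12 the median was 6083 and 3945 reads, and the highest 8230 and 5478. Among compared tags, 57 of 63 with the motif 4 nt in and 47 of 56 with it 5 nt in lay above the median tag. Ribosomal RNA ends differed in direction. Plant-type 5.8S was 1.07-fold more frequent in the colonised library. The 18S start was 5.48-fold more frequent in the non-colonised library, with 4910 colonised and 19157 non-colonised reads. Of 3 compared 18S tags, 1 lay above the median tag and 2 below. The large subunit start was 2.01-fold more frequent in the non-colonised library, with 942 and 1346 reads.

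Among tags with at least 10 reads, the number with a partner further downstream was set against the mean of the adjacent spacings. In the colonised library this ratio was 1.03 at 3 nt and 1.02 at 6 nt, against 0.962 at 4 nt and 0.976 at 5 nt. In the other library it was 0.989 at 3 nt and 1.00 at 6 nt, against 0.962 at 4 nt and 0.987 at 5 nt. Periodicity was not tested. Undetermined bases were concentrated at 2 positions of the non-colonised library, position 5 with 43777 reads and position 18 with 41974 reads, against 40 and 91 reads in the colonised library.

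All 3 tests on miR396 were chosen after the result was seen. Over 21 sites with and without the bulge its log2 ratio was -1.27 (95% interval -1.33 to -1.20). The scaling of the libraries did not remove it, at -0.96 with median-ratio scaling, nor did leaving out the most abundant tag, at -1.12. A lower yield of all cleavage products as the whole cause is argued against by the other listed families, since 8 of 9 with at least 50 reads had an interval wholly above that of miR396. A part in it was not excluded. The median of 40 sites of the other families lay 0.91 above the median of 15 miR396 sites on the log2 scale, with a bootstrap interval of 0.07 to 1.59. Fewer target transcripts, less cutting by miR396 and a difference between these 2 preparations all stay open, since transcript levels were not measured here and colonisation was compared in 1 library each, so no biological explanation was tested.

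The reads pairing with miR171 lay 3 nt upstream of the position opposite nt 10. The position was singled out from the read counts, and both tests were set after that but before the tags there were examined. The test of one unrelated abundant transcript did not decide, because the most abundant tag held 47.0% of the 1067 reads and 2 tags had at least 20 reads, between the bounds set. A miR171 form that starts 3 nt further downstream may have made these cuts, as a hypothesis, since 96.3% of the reads also paired with nt 8 to 10 of that form. The same pairing would follow from any cut inside a miR171 site, and the small RNAs of these roots were not analysed here.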
